A study of Homo sapiens with 2 samples.

How the data were processed

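Total RNA from HepG2, an established human liver cancer line that makes many plasma proteins, was profiled by RNA sequencing 48 h after transfection with siRNA against AUF1 or with control siRNA. AUF1 is an RNA-binding protein that binds AU-rich elements, and its gene is HNRNPD. The series holds 2 libraries, 1 per group, named here siAUF1 and siCtrl after the treatment labels. Per the labels' protocols, ribosomal RNA was depleted and strand-marking libraries were made with dUTP and random hexamers, so RNAs without a poly(A) tail were also captured.

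The authors deposited 1 FPKM value per gene and library (fragments scaled to transcript length and to the mapped fragments of the library). TopHat2, a spliced aligner, and Cufflinks, a transcript quantifier, are named without versions in the submitters' processing notes, as is the genome build hg19. The headers do not name the unit, and FPKM was inferred from Cufflinks and from the deposited values, which were not whole numbers and summed to 399769 in siAUF1 and 401403 in siCtrl. The annotation, and whether strand was used in counting, are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be assigned with certainty. Each file lists the same 22923 Ensembl gene IDs, and no ID was at 0 in both libraries. Of these IDs, 1800 were at 0 in siAUF1 and 1723 in siCtrl.

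Gene symbols came from a table of current names, which matched 22564 IDs, and then from GENCODE release 29, which brought the number with a symbol to 22754. The remaining IDs were kept under their ID. GENCODE release 29 is on another build than the one named by the submitters, so no coordinates are given, and the release was used only for names, gene types and transcript sequences. The 40 rows that shared a symbol with another row were summed, which left 22901 genes.

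FPKM values hold no read counts, and with 1 library per group neither a count model nor any other test of the conditions can be made. No p-value is therefore given, and differences describe these 2 libraries only. The total depth is unknown, and no counting interval can be given. Values near 1 FPKM are less precise than those of abundant genes.

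For each gene the log2 ratio log2((siAUF1 FPKM + 1)/(siCtrl FPKM + 1)) was computed, which understates the change of genes with low values. Folds given beside it are ratios of the FPKM values without the added 1. Genes with a mean of at least 1 FPKM over both libraries were kept, 12643 in all, of which 10949 were protein-coding. In place of a test a fixed size rule was used: a log2 ratio of at least 1 in size, called 2-fold here. The median log2 ratio of the kept genes was 0.03, and 0.04 for genes with a mean of at least 5 FPKM. No rescaling was applied.

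A set of 34 gene lists was fixed before the data were examined, covering RNA-binding proteins, hepatocyte functions, lipid metabolism, stress pathways, cell division and markers of other cell types. Lists with at least 5 kept genes, 30 in all, were described by their median log2 ratio and its percentile among 10000 random lists of the same size, in which each member was replaced by a gene from the same of 20 bins of mean FPKM. A list is said to stand apart below percentile 2.5 or above percentile 97.5. Chance would place 1.5 of 30 independent lists there. Members of a pathway vary together, so random lists understate the spread, and the percentile describes these libraries and does not test the siRNA.

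The genes named were also chosen by rule before the data were examined. They were HNRNPD, the 10 kept genes with the largest and the 10 with the smallest log2 ratio, the 5 with the largest positive and the 5 with the largest negative difference in FPKM, the 4 members with the largest log2 ratio in size of each list that stands apart, and at most 2 of any other list. Left out of the rankings over all genes, by the start of the symbol, were SNOR, SCARNA, RNU, RNY, RN7S, RNA5, MIR, LOC, LINC and clone names, as well as histones, IDs without a symbol, XIST and Y-linked genes. Other structural RNAs, such as RPPH1 and 7SK, stayed in. Some genes that the rule takes are not reported here. Members named outside this rule are said to have been chosen after their values were seen.

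Alternatives were another pseudocount (0.1 or 5), another filter (0.1, 5 or none), 3 rescalings of the libraries, the highest row per symbol in place of the sum, other fold sizes (1.5 or 4), unmatched random lists and means in place of medians. Removing genes listed at 0, removing a trend on GC content and transcript length, and leaving out members shared between lists were added after the data were seen. The scripts were tested on simulated data for siAUF1 against siCtrl with 12672 kept genes and a noise SD of 0.2 (log2) per library. The 2-fold rule took 4% of genes changed 1.5-fold, 72% of those changed 2.5-fold, 98% of those changed 4-fold and 3 unchanged genes. A list shifted by -0.4 gave a median of -0.386 below all random lists, and 4.75% of 400 unshifted random lists fell outside the band. The log2 ratios of the real libraries had an SD of 0.348, which spans both libraries, any real differences and APOB. It is therefore not the same measure as a noise SD per library. The noise was a chosen setting and was not estimated from these libraries. The 3 unchanged genes therefore give no rate of false calls for them. Simulated genes varied independently, so the 4.75% does not cover lists whose members vary together. Computations used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots used matplotlib 3.10.9.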

Results

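Gene expression was measured by RNA sequencing of ribosomal RNA-depleted total RNA from HepG2 cells 48 h after siRNA transfection. The design compared 1 library from cells given AUF1 siRNA (siAUF1) with 1 library from cells given control siRNA (siCtrl), and asked which transcripts differ when AUF1 is depleted. There were no replicates, so no value has a replicate error, and whether a difference exceeds the spread between cultures could not be determined. At least 1 FPKM was reached by 12610 listed genes in siAUF1 and 12712 in siCtrl. The 20 highest rows held 15.4% of the summed FPKM in siAUF1 and 17.9% in siCtrl.

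The targeted transcript was lower in the library labelled as its knockdown. HNRNPD (ENSG00000138668), which encodes AUF1, stood at 10.03 FPKM in siAUF1 and 38.0 FPKM in siCtrl, 26.4% of the control value, with a log2 ratio of -1.82. It ranked 5 from the lowest ratio among 12643 genes with a mean of at least 1 FPKM. Its paralog HNRNPDL, named outside the rule for genes, stood at 55.3 FPKM in siAUF1 and 61.7 FPKM in siCtrl, a log2 ratio of -0.15.

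Among single genes, the strongest differences included lower AKR1B10, an aldo-keto reductase, and higher TPM4, a tropomyosin of the actin cytoskeleton. In all, 51 genes were at least 2-fold higher and 73 at least 2-fold lower in siAUF1, which is 0.981% of the genes kept. Such counts use the log2(FPKM + 1) scale, and folds of single genes are ratios of FPKM, so a gene with a low value can have a fold over 2 and not be counted. Of these, 39 of the higher and 66 of the lower genes were protein-coding. AKR1B10 (ENSG00000198074) was 4.36-fold lower, at 34.4 against 149.9 FPKM. PTGDR2, a prostaglandin D2 receptor, was 9.12-fold lower at 1.05 against 9.54 FPKM. DSC2, the desmosomal cadherin desmocollin 2, was 4.68-fold lower at 2.43 against 11.4 FPKM. NDUFAF3, an assembly factor of respiratory complex I, was 5.0-fold lower at 1.56 against 7.79 FPKM, and ETNK2, an ethanolamine kinase, was 3.42-fold lower at 6.57 against 22.5 FPKM. NAALADL1 and LACTBL1 had log2 ratios of -1.69 and -1.63 at means of 3.58 and 2.90 FPKM. The processed pseudogene ACSL3P1 had a log2 ratio of -1.76 while its parent gene ACSL3, which could share its reads, stood at 120.4 and 119.9 FPKM.

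On the higher side, TPM4 (ENSG00000167460) was 3.49-fold higher at 124.5 against 35.7 FPKM. TAGLN, the actin-binding protein transgelin, was 3.09-fold higher at 15.6 against 5.05 FPKM. NOLC1, a nucleolar phosphoprotein, was 3.15-fold higher at 26.2 against 8.31 FPKM, and OGFR, the opioid growth factor receptor, was 3.37-fold higher at 26.2 against 7.77 FPKM. VCAN, the matrix proteoglycan versican, was 3.53-fold higher at 5.65 against 1.60 FPKM. PLA2G12A, a secreted phospholipase A2, was 3.08-fold higher at 8.29 against 2.69 FPKM. The metallothionein MT1H, which can share reads with close copies, was 4.53-fold higher at 7.03 against 1.55 FPKM. RF02164, annotated as a miscellaneous RNA, had a log2 ratio of 1.57 at a mean of 3.06 FPKM.

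Some entries among the extreme ratios were uncertain, and the genes that overlap them were chosen after the values were seen. APOB, the structural protein of very low density lipoprotein, was listed at 0 in siCtrl and at 1852 FPKM in siAUF1, and no fold is given for it. It was the only gene with a mean of at least 1 FPKM that was listed at 0 in either library, and without it the count of higher genes was 50. The read-through gene NDUFC2-KCTD14 stood at 0.296 FPKM in siAUF1 and 21.9 FPKM in siCtrl, while the genes it overlaps were both higher in siAUF1, NDUFC2 at 97.8 against 74.6 FPKM and KCTD14 at 7.81 against 5.65 FPKM. The read-through gene RPS10-NUDT3 stood at 8.16 and 1.18 FPKM beside RPS10 at 681.4 and 646.4 FPKM and NUDT3 at 17.8 and 12.9 FPKM. Summed with NDUFC2, NDUFC2-KCTD14 stood at 98.1 FPKM in siAUF1 and 96.5 FPKM in siCtrl, close between the libraries. Summed with KCTD14 it stood at 8.11 and 27.6 FPKM. RPS10-NUDT3 summed with RPS10 stood at 689.5 and 647.6 FPKM, and with NUDT3 at 25.95 and 14.12 FPKM. How reads were split between these overlapping genes is not known.

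By absolute level, APOB apart, the largest differences upward in siAUF1 were those of ACTG1 (1680 against 1157 FPKM), a cytoplasmic actin, NPM1 (1458 against 1003 FPKM), the nucleolar protein nucleophosmin, EEF1A1 (3184 against 2755 FPKM), a translation elongation factor, and PEG10 (1380.2 against 1102 FPKM), an imprinted retrotransposon-derived gene. Among genes that the naming rule ranks, the largest differences downward were those of the RNase P RNA RPPH1 (5352 against 6730.4 FPKM), APOA1 (1245 against 2127 FPKM), 7SK (4513 against 5385 FPKM), AHSG (784 against 1530 FPKM, the plasma protein fetuin-A) and MALAT1 (2254 against 2879 FPKM, a nuclear noncoding RNA). Some RNAs that the rule leaves out by symbol differed by more, and were chosen after their values were seen: RN7SL1 (6794 against 10517.5 FPKM) and RN7SL2 (4700.1 against 6311 FPKM), copies of the signal recognition particle RNA, by more than RPPH1, and RN7SK (4202 against 5369 FPKM) by more than APOA1. RN7SK and 7SK are names of the same RNA listed under separate IDs, which can share reads, so their differences are not separate results. ACTG1, NPM1 and EEF1A1 have many processed pseudogenes that can share their reads.

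**Figure D1:**
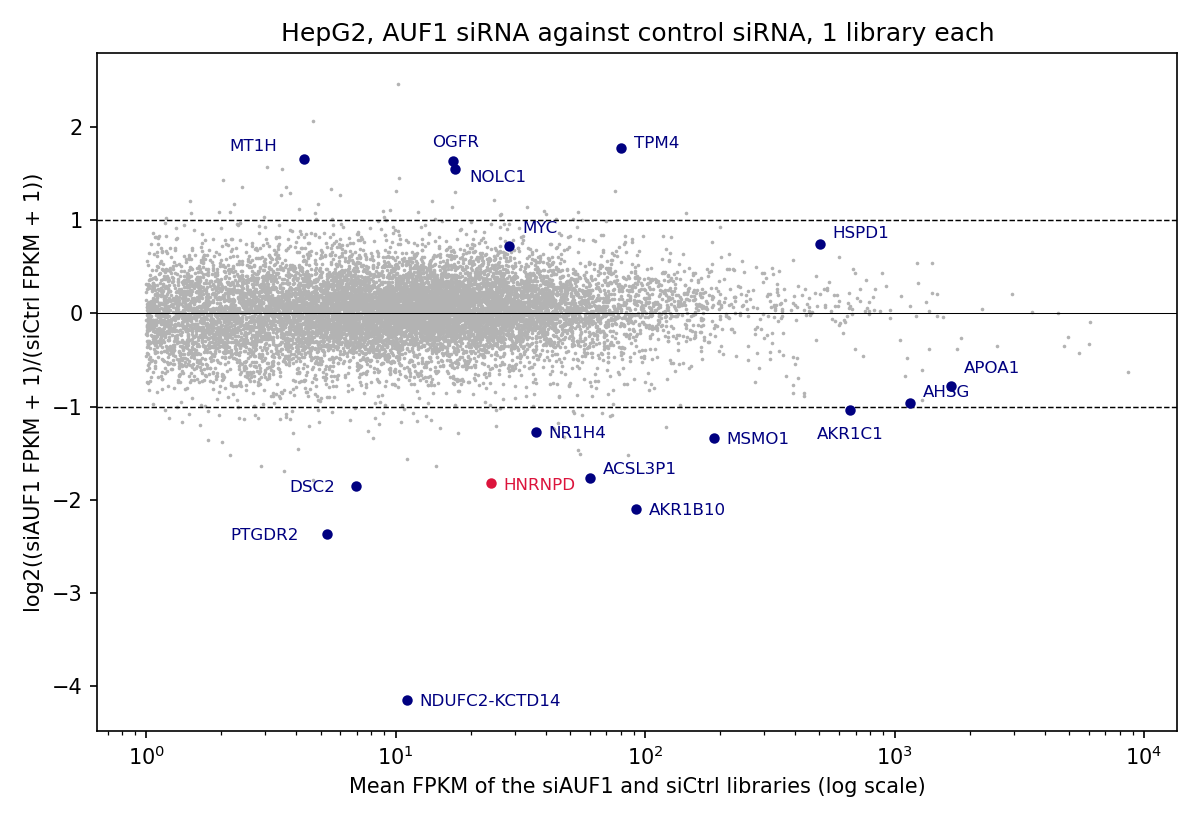
Log2 ratio of siAUF1 to siCtrl (FPKM + 1) against the mean FPKM of both libraries on a log axis, 1 point per gene with a mean of at least 1 FPKM and a value above 0 in both libraries, so APOB is not drawn. Dashed lines mark the 2-fold rule; HNRNPD (red) lies at -1.82 and AKR1B10 at -2.09, while most genes lie close to 0.

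Of the 30 gene lists with enough expressed members, 13 stood apart from expression-matched random lists, 5 with lower and 8 with higher values in siAUF1, where chance would give 1.5 if lists were independent. The lower lists covered cholesterol synthesis and uptake, hepatocyte secreted proteins, fatty acid and triglyceride synthesis, NRF2 target genes, and bile acid and drug metabolism. The higher lists covered the heat shock response, replication-dependent histones, p53 target genes, mitosis, mRNAs known as AUF1 targets, ATF4 target genes, DNA replication and the hnRNP family. Each of the 3 rescalings of the libraries shifted siAUF1 down by at most 0.05 (log2). A single factor moves a list among random lists only through the added 1 and the filter, so it hardly tests a list's place there. It moved some members across 0 and turned some medians near 0 among the other lists. Counts of members after rescaling keep the genes that passed the filter as deposited.

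**Figure D2:**
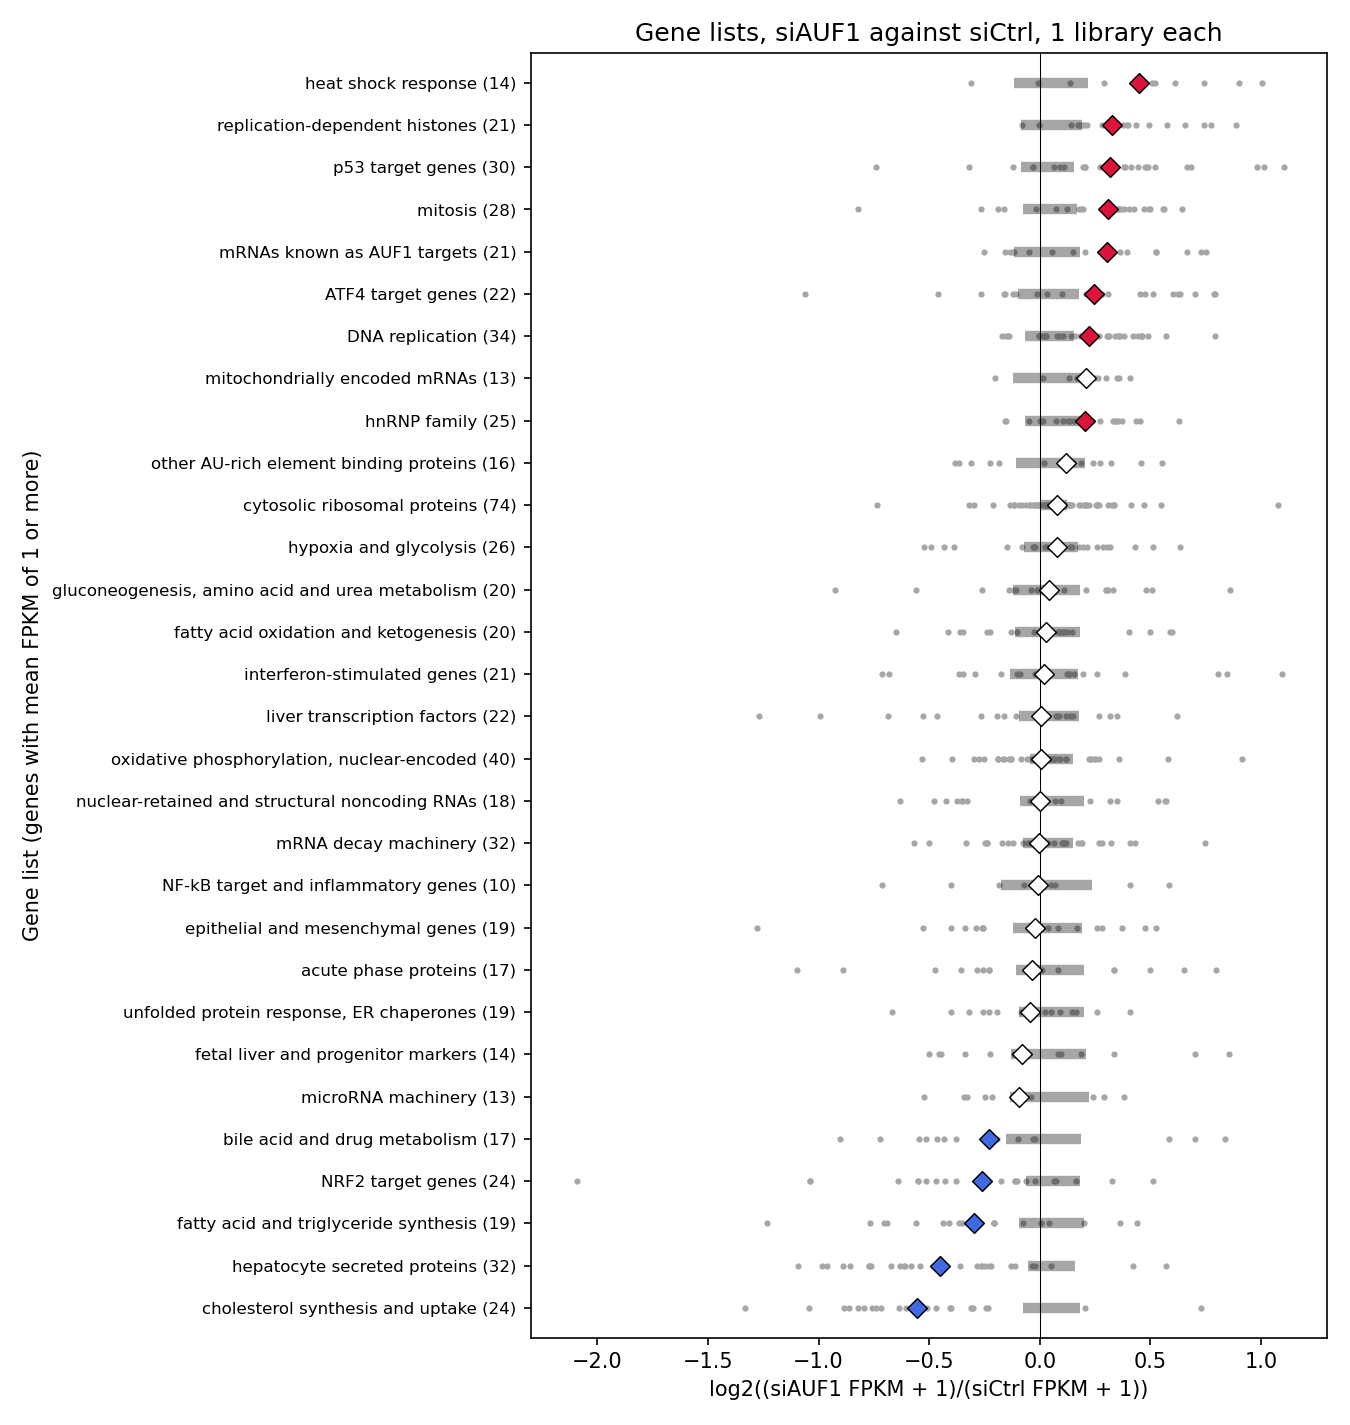
Log2 ratio of siAUF1 to siCtrl (FPKM + 1) for 30 gene lists fixed in advance, with the number of genes in parentheses. Grey points are genes (APOB is not drawn), diamonds are list medians (blue, low lists that stand apart; red, high lists that stand apart; white, others), and grey bars span the central 95% of medians of 10000 matched random lists; cholesterol synthesis and uptake has the lowest median at -0.56 and the heat shock response the highest at 0.45.

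Genes of cholesterol synthesis and uptake were lower in siAUF1 almost throughout. The median log2 ratio of the list was -0.56, below all 10000 random lists, with 22 of 24 members lower and 2 of them at least 2-fold lower. MSMO1, a sterol C4-demethylation enzyme, was 2.53-fold lower at 106.9 against 270.5 FPKM, and LSS, lanosterol synthase, was 2.09-fold lower at 33.3 against 69.5 FPKM. STARD4, a sterol carrier, was 1.84-fold lower. Among members chosen after their values were seen, HMGCS1, which makes HMG-CoA, stood at 79.2 against 138 FPKM. PMVK, phosphomevalonate kinase, was among the members that were higher, at 4.12 against 2.09 FPKM.

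Fatty acid and triglyceride synthesis genes were lower as a list as well, by less. Their median was -0.30, below all random lists, with 14 of 19 members lower (15 or 16 after rescaling) and 1 at least 2-fold lower. ACSS2, which makes acetyl-CoA from acetate, was 2.41-fold lower at 25.01 against 60.2 FPKM. GPAM and DGAT1, enzymes of triglyceride synthesis, were 1.72-fold and 1.65-fold lower, and the desaturase SCD was 1.62-fold lower at 314.3 against 508 FPKM. The fatty acid oxidation and ketogenesis list did not stand apart: its median of 0.03 lay at percentile 44.2, with SLC25A20 at a log2 ratio of -0.65 and CPT1A at 0.60.

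Genes for plasma proteins made by hepatocytes were lower in siAUF1. The median of the list was -0.45, below all random lists, with 28 of 32 members lower. Its mean was -0.08, at percentile 3.82, because the entry of APOB at 0 in siCtrl gives that gene a log2 ratio of 10.9. VTN, vitronectin, was 2.17-fold lower at 35.3 against 76.5 FPKM. APOC3, an apolipoprotein that slows triglyceride clearance, was 1.99-fold lower at 92.1 against 183.5 FPKM, and AHSG was 1.95-fold lower. Among members chosen after their values were seen, albumin (ALB) stood at 1675 against 2015 FPKM, while APOA2, at 2285 against 2205 FPKM, and the fibrinogen chain FGG, at 1549.7 against 1589 FPKM, were close between the libraries.

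The bile acid and drug metabolism list had a median of -0.23 at percentile 0.32, with 14 of 17 members lower. CYP27A1, the sterol 27-hydroxylase of bile acid synthesis, was 1.66-fold lower at 47.1 against 78.4 FPKM. The other 3 members with the largest ratios were close to 1 FPKM: CYP8B1 had a log2 ratio of -0.91, GSTA2 of 0.84 and CYP3A5 of 0.70. With the filter lowered to a mean of 0.1 FPKM the list no longer stood apart (median -0.10, percentile 5.83).

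Liver transcription factors did not stand apart as a list, with a median of 0.01 at percentile 33.5, 12 of 22 members higher and 10 lower, which each rescaling turned to 10 higher and 12 lower with medians from -0.02 to -0.04. Their mean was -0.11, at percentile 1.96 of random lists, and 2 members differed by about 2-fold. NR1H4, the bile acid receptor FXR, was 2.48-fold lower at 21.1 against 52.2 FPKM, and CEBPA, a liver-enriched transcription factor, was 2.04-fold lower at 23.4 against 47.6 FPKM. Acute phase proteins had a median of -0.04 at percentile 11.4, with HP, haptoglobin, whose reads its close copy HPR can share, 2.16-fold lower and FGA, a fibrinogen chain, 1.85-fold lower. Over genes with a mean of at least 5 FPKM the acute phase list did stand apart, with a median of -0.13 at percentile 1.06. At the filter of 1 FPKM, and without the members that another list also holds, its median was 0.05 at percentile 50.15. Fetal liver and progenitor markers had a median of -0.08 but a mean of 0.0015, at percentile 7.68 by the median, with CD24 at a log2 ratio of 0.85 and SALL4 at 0.70. The list for gluconeogenesis, amino acid and urea metabolism had a median of 0.04 at percentile 56.9, with GPT, alanine transaminase, at -0.92 and PCK2, mitochondrial PEP carboxykinase, at 0.86.

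Genes known as NRF2 targets, which serve redox and xenobiotic defence, were lower in siAUF1, with aldo-keto reductases at the head. The median of the list was -0.26, below all random lists, with 19 of 24 members lower and 3 at least 2-fold lower. These 3 were AKR1B10, AKR1C2 (2.12-fold lower, 16.1 against 34.2 FPKM) and AKR1C1 (2.06-fold lower, 435.4 against 895 FPKM). PGD, of the pentose phosphate pathway, was 1.56-fold lower. The close paralog AKR1C3, chosen after its values were seen, stood at 109.3 against 97.48 FPKM. AKR1C1 and AKR1C2 are nearly identical in sequence, so the split of reads between them is uncertain.

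Target genes of the tumour suppressor p53 were higher in siAUF1. Their median was 0.32, above all random lists, with 25 of 30 members higher and 2 at least 2-fold higher. BTG2, an antiproliferative gene, was 2.36-fold higher at 12.5 against 5.28 FPKM, BBC3, which encodes the pro-apoptotic protein PUMA, was 2.37-fold higher at 6.73 against 2.84 FPKM, and FDXR, ferredoxin reductase, was 2.05-fold higher at 26.9 against 13.1 FPKM. TP53INP1 went the other way, 1.73-fold lower at 12.5 against 21.5 FPKM. Chosen after its values were seen, the p53 ubiquitin ligase gene MDM2 stood at 126 against 129 FPKM.

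Genes of cell division were also higher as lists. Mitosis genes had a median of 0.31, above all random lists, with 23 of 28 higher, and DNA replication genes had a median of 0.22 at percentile 99.9, with 27 of 34 higher (23 of 34 after each rescaling). No member of either list was 2-fold higher or lower. CENPF, a kinetochore protein, was 1.60-fold higher, AURKB 1.502-fold and BUB1B 1.51-fold, whereas the mitotic kinase AURKA was 1.78-fold lower at 53.4 against 95.2 FPKM. CDC7, a kinase that fires replication origins, was 1.83-fold higher at 14.3 against 7.80 FPKM. CDC45 was 1.53-fold higher, GINS4 1.47-fold and RRM1, a subunit of ribonucleotide reductase, 1.42-fold. Replication-dependent histones had a median of 0.33 at percentile 99.99, with 19 of 21 higher. H1-5 was 1.91-fold, H2BC5 1.72-fold, H4C5 1.69-fold and H4C8 1.58-fold higher, with reads that close histone copies can share.

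Chaperones of the heat shock response had the highest median of the 30 lists fixed in advance, 0.45, above all random lists, with 12 of 14 members higher. HSPB1, a small heat shock protein, was 2.04-fold higher at 74.8 against 36.7 FPKM, and HSPA4L was 1.996-fold higher at 13.3 against 6.66 FPKM. The mitochondrial chaperonin HSPD1 was 1.68-fold higher at 630.9 against 376.3 FPKM, and HSP90AB1 was 1.53-fold higher at 721 against 472.1 FPKM. ATF4 target genes had a median of 0.24 at percentile 99.7, with 14 of 22 higher (13 or 14 after rescaling). MTHFD2, of mitochondrial folate metabolism, was 1.75-fold and TRIB3, a pseudokinase, 1.74-fold higher, while PHGDH, the first enzyme of serine synthesis, was 2.12-fold lower at 43.0 against 90.9 FPKM. ALDH1L2 was close to 1 FPKM, at 1.66 against 0.640 FPKM. Its fold was 2.60 but its log2 ratio of 0.70 did not reach the 2-fold rule. The unfolded protein response list, by contrast, had a median of -0.04 at percentile 8.87, with XBP1 1.59-fold lower and SDF2L1 at a log2 ratio of 0.41.

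mRNAs known as AUF1 targets were higher in siAUF1 by their median, 0.30 at percentile 99.97, with 15 of 21 members higher and none past 2-fold. With a pseudocount of 5 the median was 0.17, at percentile 99.64. JUND, an AP-1 subunit, was 1.70-fold higher at 52.8 against 31.0 FPKM. MYC, a growth-promoting transcription factor, was 1.69-fold higher at 35.9 against 21.3 FPKM, and the cyclin-dependent kinase inhibitor gene CDKN1A was 1.61-fold higher at 33.4 against 20.7 FPKM. The telomerase gene TERT was 1.67-fold higher at 3.18 against 1.91 FPKM. CCND1, chosen after its values were seen, stood at 78.5 against 86.1 FPKM.

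Other hnRNP genes were slightly higher, with a median of 0.20 at percentile 99.1 and 22 of 25 above 0 (19 of 25 after each rescaling). HNRNPH2 was 1.57-fold, HNRNPA1 1.37-fold, HNRNPM 1.35-fold and HNRNPR 1.296-fold higher. HNRNPA1 has many processed pseudogenes that can share its reads. With means in place of medians the list lay at percentile 97.29, inside the band. The random lists could draw APOB, whose log2 ratio of 10.9 raises their means, and its effect on this percentile was not tested. Other AU-rich element binding proteins had a median of 0.12 at percentile 82.5, with ZFP36L1 at 0.55 and YBX1 at 0.46. The microRNA machinery had a median of -0.10 at percentile 6.46, with AGO2 at -0.52 and XPO5 at 0.38, and the mRNA decay machinery had a median of -0.0022 (mean 0.022) at percentile 22.4, with the decapping enzyme gene DCP2 at 0.75 and CNOT8 at -0.57.

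The remaining lists did not stand apart. Interferon-stimulated genes had a median of 0.02 at percentile 51.7, although BST2, tetherin, was 2.18-fold higher at 54.0 against 24.7 FPKM and MX2 1.91-fold higher. The NF-kB and inflammatory list had a median of -0.01 at percentile 32.2, with IRF1 at -0.71 and NFKB1 at 0.58. Hypoxia and glycolysis genes had a median of 0.08 at percentile 66.9, with CA9 at 0.63 and BNIP3 at -0.52. Nuclear-encoded oxidative phosphorylation genes had a median of 0.0033 at percentile 17.1, with SDHB at 0.58. Mitochondrially encoded mRNAs had a median of 0.21 at percentile 95.6, with 12 of 13 higher (11 of 13 after each rescaling), MT-ND2 at 0.41 and MT-ND1 at 0.36. Cytosolic ribosomal protein genes had a median of 0.08 at percentile 61.9, with RPL11 at 1.08 and RPS27 at -0.74. Nuclear-retained and structural noncoding RNAs had a median of 0.0022 but a mean of -0.014, at percentile 20.7 by the median, with RN7SL1 1.55-fold lower and SNHG8 at 0.57. Epithelial and mesenchymal genes had a median of -0.02 at percentile 19.9, with CDH1, E-cadherin, 3.20-fold lower at 1.85 against 5.91 FPKM and OCLN at -0.53.

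Most markers of cell types other than hepatocytes lay under a mean of 1 FPKM, and each of their 3 lists held fewer than 5 genes above it. Of the fibroblast markers PDGFRB stood at 8.56 FPKM in siAUF1 and 9.25 FPKM in siCtrl. Of the endothelial markers, EGFL7 stood at 0.895 and 2.12 FPKM and LYVE1 at 1.29 and 1.52 FPKM. Of the leukocyte and Kupffer cell markers, CD74 stood at 24.3 and 42.6 FPKM and CD14 at 0.591 and 1.42 FPKM. Of members chosen after their values were seen, LYZ stood at 600.8 and 783.9 FPKM, whereas PTPRC was at 0.00799 FPKM in siAUF1 and listed at 0 in siCtrl.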

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

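With 1 library per group no replicate could be left out, and no paired analysis was possible because the groups hold 1 library each. Depth is unknown, and it limits most the genes near 1 FPKM. HNRNPD stayed at least 2-fold lower under each of its alternatives, with log2 ratios from -1.52 to -1.91. Of 51 genes higher and 73 lower by 2-fold, a pseudocount of 0.1 made 135 and 185, a pseudocount of 5 made 13 and 24, and a filter at a mean of 5 FPKM 31 and 44. At 1.5-fold there were 502 and 491 genes, and at 4-fold (log2(FPKM + 1) scale) 3 and 3; these shifts follow from the construction of each setting. Of the 3 at 4-fold higher, RNU1-3, a U1 RNA copy named after its value was seen, joins APOB and RPS10-NUDT3. The 3 lower were NDUFC2-KCTD14, PTGDR2 and AKR1B10. APOB and both read-through genes are the entries called uncertain in the results. The 3 rescalings multiplied siAUF1 by 0.969 to 0.980 and moved neither count by over 1.5 times. For the 13 gene lists that stood apart, 110 results under the alternatives were counted, and 106 of these stayed on the same side of the band. Rescalings were not counted, because they move a list among random lists only through the added 1 and the filter. Interferon-stimulated genes, for example, went from percentile 51.7 to 59.3 when the median log2 ratio was set to 0. Results with the highest row per symbol, without genes at 0 or without shared members were left out where a list's median stayed the same. This held even where members had been removed. By this count 10 lists stayed on their side throughout, though the median of mRNAs known as AUF1 targets went from 0.30 to 0.17 with a pseudocount of 5. An exception was bile acid and drug metabolism with a filter at 0.1 FPKM (-0.10) or none (-0.037, percentile 18.1), which bring in genes with low values. With means in place of medians, further exceptions were hepatocyte secreted proteins (-0.0751), where APOB sets the mean, and the hnRNP family (0.19). For the hnRNP family the random lists could draw APOB, which raises their means, and its effect was not tested. Among the other lists, acute phase proteins at a mean of at least 5 FPKM (-0.13) stood apart, and the cause was not tested. Liver transcription factors stood apart with means (-0.11) against a median of 0.01. Their 2 largest ratios in size, NR1H4 at -1.27 and CEBPA at -0.99, weigh on the mean and not on the median. At the filter of 1 FPKM the acute phase median went from -0.04 to 0.05 without shared members, inside the band in both cases. The number of lists that stood apart ranged from 12 to 14. Removing genes at 0, removing the GC and length trend, and leaving out shared members were chosen after seeing the data.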

Other observations

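The gene groups in this paragraph and the next were drawn up after the largest differences had been seen, so they describe these 2 libraries and do not test them. Genes among those differences, such as NOLC1, NPM1 and MT1H, were kept in their lists, so the percentiles can partly reflect them. Ribosome biogenesis factors were higher in siAUF1 in all 34 of 34 members with a mean of at least 1 FPKM, with a median log2 ratio of 0.48, above all 10000 matched random lists (whose central 95% lay between -0.06 and 0.15). DKC1, the pseudouridine synthase of box H/ACA particles, stood at 38.4 against 23.2 FPKM, POLR1B, a subunit of RNA polymerase I, at 25.9 against 15.2 FPKM, and NCL, nucleolin, at 162.3 against 112.2 FPKM. Aminoacyl-tRNA synthetases were higher in 20 of 20 members, with a median of 0.31 at percentile 99.99, for example KARS1 at 103 against 61.3 FPKM. Proteasome subunits had a smaller median of 0.17 at percentile 97.9, with 27 of 31 higher (24 to 26 after rescaling), and CCT chaperonin subunits 0.29 at percentile 98.4, with 7 of 8 higher (6 of 8 after each rescaling). The counts of 34 and 20 held under the 3 rescalings of the libraries.

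Metallothioneins, small metal-binding proteins, were higher in 7 of 7 members, rescaled or not, with a median log2 ratio of 1.02 above all random lists. MT2A stood at 73.7 against 34.1 FPKM, MT1G at 108.2 against 42.9 FPKM and MT1E at 262.7 against 137.6 FPKM, while MT1F was close at 30.4 against 29.5 FPKM; these near-identical genes can share reads. Tubulins had a median of 0.53 above all random lists, with 10 of 11 higher, TUBB3 at 126.5 against 70.5 FPKM among them. Actin cytoskeleton genes and targets of the transcription factor SRF had a median of 0.21 at percentile 98.99, with 17 of 21 higher. Its members TPM4, TAGLN and ACTG1 were among the largest differences seen before the list was drawn up. The percentile therefore partly reflects these genes and is no separate support. ACTA2 stood at 14.7 against 5.35 FPKM, beside the higher TPM4 and TAGLN, while ACTN4 stood at 77.0 against 103.5 FPKM.

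The tests on the scaling of the libraries and on APOB below were chosen after the values had been seen. Those on GC content and length, AU-rich elements and FXR targets were set before their results were seen. The one on FXR targets was set after the value of NR1H4 had been seen. The first pattern is the lower level of 5 lists, of lipid synthesis, plasma proteins, NRF2 targets and bile acid and drug metabolism. The median log2 ratio of all genes with a mean of at least 1 FPKM was 0.03 (0.0286). FPKM is already scaled to the mapped fragments of each library, so a median near 0 was likely beforehand and does not test scaling. A single factor for every gene can move a list among random lists only through the added 1 and the filter, so scaling of that kind does not account for it. After a trend on GC content and transcript length was removed, which took a share of 0.00824 of the variance over 12588 of 12643 genes, 5 of these 5 lists stayed below percentile 2.5. AUF1 depletion, another effect of the siRNA and a difference between the 2 cultures stay open and untested, with 1 library each.

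The second pattern is that p53 targets, among them genes that restrain division, and genes of mitosis and DNA replication were higher in the same library. The median of all genes, 0.0286, does not test scaling here either, and a single factor again cannot set a list's place among random lists. After the GC and length trend was removed, 3 of these 3 lists still stood apart. FPKM of mixed cells cannot show whether the same cells carry both. The siRNA and the culture again remain open.

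The third pattern is the 0 for APOB in siCtrl. A candidate explanation is a failed estimate of a locus with very many fragments: by FPKM times the length of the longest annotated transcript, APOB (14121 nt) ranked 1 in siAUF1, at 26150 FPKM times kb. MALAT1 came close in siCtrl, at 25070, and was not listed at 0. TF reached 32110 in siCtrl without being at 0, though through a 20602 nt transcript whose share of the TF reads is unknown, so the explanation stays open.

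If AUF1 destabilised mRNAs with AU-rich elements widely, genes with such elements would be higher in siAUF1. Among 10857 genes with an annotated 3' UTR, the 3768 with the motif TATTTAT had a median log2 ratio of 0.01, at percentile 36.9 of sets without the motif matched on expression and 3' UTR length (whose central 95% lay between 0.0025 and 0.025). With ATTTA at 3 or more places, the median of the 3848 genes that could be matched was 0.03, at percentile 68.4. Without matching, genes with a motif had lower medians than genes without it. These were 0.012 against 0.045 for TATTTAT, and 0.015 against 0.049 for the 5009 genes with ATTTA at 3 or more places. Both matched medians lay inside the range of matched sets, so no shift of the class was detected, and effects on some of its members stay open. NR1H4, which encodes FXR, was 2.48-fold lower, and a hypothesis was that FXR target genes would be lower too. Some of these targets, such as C3, ABCB4, UGT2B4 and NR0B2, also belong to lists fixed in advance, so the FXR list is not independent of them. The 14 expressed targets had a median of -0.15 at percentile 2.58, short of the limit of 2.5 set beforehand. SLC51B stood at 4.23 against 9.55 FPKM but NR0B2 at 44.2 against 40.1 FPKM, so the data do not decide it.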
